A study of Homo sapiens with 3 samples.

How the data were processed

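Total RNA from the MHCC97Low hepatocellular carcinoma line and its cisplatin-resistant and doxorubicin-resistant sublines was measured with 1 array per line. Per the labels' protocols, cells were grown in DMEM with 10% FBS and received no treatment, RNA was extracted with Trizol, and 1 µg of RNA with integrity numbers of 8.8 to 9.5 was amplified into biotin-labelled cRNA with an Ambion MessageAmp II kit, with a mean yield of 22.1 µg (17.6 to 26.4 µg). The cRNA was hybridised to human U133 Plus 2.0 arrays from Affymetrix, per the labels. The lines were assigned to groups from the sample labels, and no drug dose or selection time was used here.

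The values analysed were deposited as a linear intensity (signal) per probe set, computed with MAS5 per the submitters' processing notes; the version is not given in the sources used here. All values were above 0, and each array's mean without the lowest and highest 2.0% of probe sets was 500.1, as found from the values, which is the form that a global scaling of each array gives. MAS5 subtracts mismatch signal probe by probe, which makes low values noisy, and global scaling assumes similar total signal in all arrays. Detection calls were not used here. All 3 value columns were used.

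Probe sets were named from the platform annotation, with symbols updated through Entrez identifiers in a RefSeq gene table of assembly GRCh38.p14, which was also used for the order of genes along chromosomes and for no coordinates. Of 54675 probe sets, 62 were controls, 41097 had 1 gene symbol, 1801 had several and were named for no gene, and 11721 are not named here. Of the probe sets with 1 symbol, 41043 (99.9%) matched the table. They represented 19775 genes, 10523 of them by several probe sets. Values under the floor, the median of all values of the 3 arrays pooled (76.9), were raised to it before log2 was taken, since low MAS5 values have no usable order. A gene was represented by its probe set with the highest mean log2 value over the 3 arrays, and its other probe sets were used to check the direction. A gene entered a comparison when at least 1 of its values was above the floor.

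Each comparison was the difference of log2 values between 2 arrays, called higher or lower at 2-fold. With 1 array per group there was no residual degree of freedom, so no p-value, and no SE or SD between samples, was computed. The precision of these values is limited by the number of arrays. As a description of spread over genes, the SD of the log2 difference estimated from the median absolute deviation was 0.358 for the cisplatin-resistant and 0.356 for the doxorubicin-resistant array against parental. It was 0.465 in the dimmest and 0.272 in the brightest of 3 equal groups of genes in the former. A list of genes was described by the median difference of its compared members (at least 3) and the percentile of that median among 10000 random lists of the same size matched on mean signal in 20 bins. The 43 lists, with 897 members of which 801 were on the array under 1 symbol and the others are not used here, covered drug transport and metabolism, DNA repair, cell death, stress, lineage, signalling, metabolism, matrix and other cell types. A list of squamous markers had 1 compared member and no median. Some genes are in several lists.

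Named genes were chosen by a rule fixed before the data were examined. It took the 8 genes in each direction with the largest difference among genes above the floor on both arrays in at least 2 probe sets, all with 1 sign, and the 4 with the largest bound in each direction among genes at or under the floor on 1 array in every probe set. It also took up to 4 members of each described list with the largest difference of at least 2-fold, and 11 transport, target and repair genes whatever their value. The direct comparison of the sublines used 5 and 2, and the overlap named 6 genes in each direction. Some genes that met the rule are not named here. Genes given as members of chromosome stretches were chosen after their values were seen.

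The overlap of both sublines was set beside independent lists and beside 200 simulations of unchanged arrays that share the parental array, with noise either normal, scaled to the median absolute deviation, or resampled from the difference between the sublines in bins of signal. Neighbouring genes were examined in windows of 15 consecutive compared genes of a chromosome, against the 95th percentile of the most extreme window in each of 1000 shuffles of gene order. The steps were tested on simulated arrays for the cisplatin-resistant against parental comparison over 12697 genes. Of 50 genes changed at each size, 14.0% passed 2-fold when changed 1.5-fold, 76.0% when changed 2.5-fold and all when changed 4-fold or 8-fold. The changed genes all had a mean log2 value more than 2 above that of the floor, so these shares do not cover dimmer genes. With normal noise, 212 unchanged genes (1.70%) passed. That noise was scaled to the median absolute deviation of the difference between the sublines, which includes any real differences between them and leaves out its wide tails. The 1.70% is therefore not a rate of array noise. A planted block of 30 neighbouring genes was recovered whole, as 1 segment.

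Alternatives fixed beforehand were quantile normalization, alignment of the median of measured probe sets, a floor at the 25th or 75th percentile or none, the floor as a pseudocount, only genes above the floor on all arrays, the median over a gene's probe sets, probe sets with the suffixes _x_at and _s_at left out, and thresholds of 1.5-fold and 4-fold. Subtraction of the median of the nearest genes on the chromosome, removal of genes in shifted stretches, and the use of the settings above on the chromosome medians were added after the data were seen, although what other scalings should show was written down before those medians were computed. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.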

Results

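The samples were 3 RNA preparations from MHCC97Low, a human metastatic hepatocellular carcinoma cell line. They comprised the untreated parental line and a cisplatin-resistant and a doxorubicin-resistant subline derived from it, with 1 array for each. Cisplatin forms DNA crosslinks, and doxorubicin is an anthracycline that poisons topoisomerase II and is a substrate of efflux pumps. Gene expression was measured on human U133 Plus 2.0 arrays from Affymetrix, which carry 54675 probe sets. There were no replicates, so no difference below could be set against a spread between cultures, no test was possible, and the number of arrays limits the precision of every value. A gene was called higher or lower at a 2-fold difference, and "at least" marks a fold whose dimmer side lay at or under the floor of 76.9 signal units.

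The 3 arrays had similar signal distributions. The median signal was 78.5 in the parental, 79.2 in the cisplatin-resistant and 73.3 in the doxorubicin-resistant array, and 12083, 12107 and 11879 genes lay above the floor. Across the 24574 probe sets above the floor on all 3 arrays, which are not independent replicates, Pearson's r of log2 signal was 0.971 between the cisplatin-resistant and parental arrays, 0.969 between the doxorubicin-resistant and parental arrays and 0.966 between the sublines. The 3' to 5' signal ratio was 1.49, 1.51 and 1.53 for ACTB and 0.954, 0.975 and 1.02 for GAPDH in the parental, cisplatin-resistant and doxorubicin-resistant arrays. The poly-A spike-in probe sets, which are added before labelling, had a median log2 difference from parental of 0.09 in the cisplatin-resistant and -0.33 in the doxorubicin-resistant array, whereas the hybridisation spikes differed by -0.01 and -0.06. The housekeeping reference genes had median log2 differences of 0.00 and -0.04.

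The first comparison asked which genes differ between the parental line and its cisplatin-resistant subline. Several secreted liver proteins were lower in the resistant subline. The iron carrier transferrin (TF) had a signal of 4925 in the parental and 234 in the cisplatin-resistant array, 21.0-fold lower, albumin (ALB) was at least 20.1-fold lower (at least 2.64-fold by its weakest measured probe set), and the fibrinogen chains FGG and FGB were at least 13.1-fold and 6.78-fold lower. The interferon-stimulated genes IFI27 and ISG20, an exonuclease, were 5.11-fold and 3.94-fold higher. HMOX1, the haem-degrading enzyme heme oxygenase, was 6.17-fold lower, while NNMT, which methylates nicotinamide, was at least 12.3-fold higher.

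Of 12710 genes compared, 360 were at least 2-fold higher and 328 at least 2-fold lower in the cisplatin-resistant array, together 5.41%. Both values were above the floor for 283 of the higher and 259 of the lower genes, and 27 genes in each direction differed by 4-fold or more. Where other measured probe sets of the gene existed, their median pointed the same way for 137 of 148 higher genes and 128 of 138 lower genes, against 69.5% of all genes. That median reached 2-fold itself for 37 and 61 of them. Among genes above the floor on both arrays in several probe sets, all with 1 direction, the higher ones were led by TNFRSF11B, the osteoprotegerin decoy receptor, at 6.49-fold (4.24 to 6.49-fold over its probe sets). They continued with the ETS transcription factor ETV1 at 4.79-fold, LRATD2 at 4.45-fold and the coxsackievirus and adenovirus receptor CXADR at 4.35-fold (4.30 to 4.70-fold). The nucleosome-binding protein HMGN5 was 3.77-fold and the glutamate transporter SLC1A7 3.42-fold higher. The corresponding lower genes included the actin nucleator SPIRE1 at 7.76-fold, the chromatin remodelling ATPase SMARCA1 at 4.32-fold, the serine protease HTRA3 at 4.23-fold, the ectodysplasin gene EDA at 4.08-fold, apolipoprotein APOH at 4.04-fold and the potassium channel subunit KCNE4 at 3.91-fold. The probe set with the smallest difference showed 1.72-fold for ETV1, 1.35-fold for LRATD2 and 1.31-fold for HMGN5. It showed 1.78-fold for EDA, 1.25-fold for APOH and 1.88-fold for KCNE4. For SPIRE1 and TF it was limited by the floor, at least 1.61-fold and at least 2.57-fold.

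Several genes crossed the floor between the parental and cisplatin-resistant arrays. MAP3K7CL was at least 60.0-fold higher, with a signal of 4614 in the resistant array, TMEM47 was at least 8.35-fold higher and the acyl-CoA synthetase ACSS3 at least 6.59-fold higher. FGF13 was at least 10.4-fold lower and the nuclear receptor corepressor NRIP1 at least 10.2-fold lower. SPIRE1 lies on chromosome 18, where 90.3% of the 175 compared genes were below the parental value. SMARCA1 and FGF13 lie in lower stretches of chromosome X, and MAP3K7CL lies at the end of a higher stretch of chromosome 21. With the median of neighbouring genes subtracted, a setting added after the data were seen, they and SPIRE1 stayed past 2-fold. Their log2 differences were then -1.91 for SPIRE1, -1.63 for SMARCA1, at most -2.93 for FGF13 and at least 5.49 for MAP3K7CL.

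**Figure D1:**
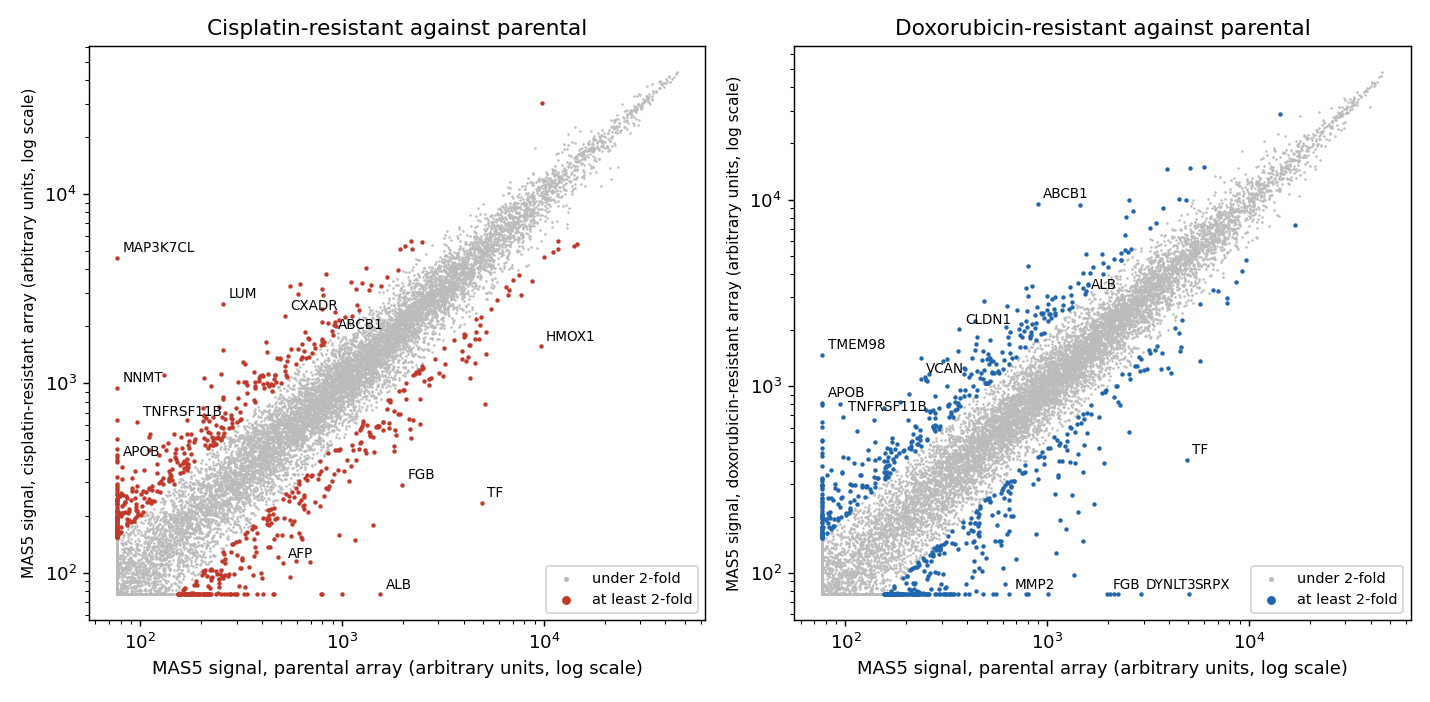
MAS5 signal of each gene in the parental array (x axis, arbitrary units, log scale) against the cisplatin-resistant array (left) and the doxorubicin-resistant array (right), with values under the floor of 76.9 drawn at the floor. Each point is a gene, coloured where it differs by at least 2-fold (688 genes on the left, 721 on the right); TF and FGB lie below the diagonal in both panels, and ABCB1 lies far above it on the right.

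Among the gene lists, the hepatocyte and fetal liver list stood furthest from parental in the cisplatin-resistant array. Its 18 compared members had a median log2 difference of -1.42, below that of all 10000 random lists matched on signal, with 10 members lower, 1 higher and 7 within 2-fold. The exception was APOB, the apolipoprotein of low-density lipoproteins, at least 5.01-fold higher. The interferon-stimulated list of 24 genes had a median of 0.44, above all random lists, with 5 members higher and none lower, including the helicase DDX60 at 2.38-fold and OASL at 2.11-fold. Antigen presentation genes had a median of 0.23, which 98.4% of random lists lay below, and none of 16 members reached 2-fold.

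Stress response, Wnt and Notch lists each had a negative median in the cisplatin-resistant array, while other stress and signalling lists stayed inside the central 95% of random lists. The unfolded protein response and ATF4 target list had a median of -0.36, below all random lists, although none of its 21 members reached 2-fold. The Wnt target and feedback list had a median of -0.36 over 12 genes, with 0.12% of random lists lower and no member at 2-fold. The Notch list had a median of -0.39 over 7 genes, with 0.53% of random lists lower and the target gene HEY1 2.48-fold lower. Fatty acid synthesis and oxidation genes had a median of 0.32, with 1 of 19 members past 2-fold, the fatty acid receptor CD36, which was at least 2.31-fold lower but under 2-fold in most alternative settings. Mitochondrial respiratory chain genes had a median of 0.12 over 24 genes, none past 2-fold. In all, 8 of 42 lists lay outside the central 95% of random lists, where 2.1 would lie if list members varied independently. Members of a list can vary together and some lists share genes, so 2.1 is not the number to be had from unchanged lines.

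Most genes tied to platinum handling were within 2-fold of parental in the cisplatin-resistant array. The copper and platinum transporters had log2 differences of -0.12 for SLC31A1, -0.17 for ATP7A and 0.08 for ATP7B, the conjugating enzyme GSTP1 -0.08, and the excision repair endonuclease subunit ERCC1 -0.32. Other probe sets were lower for some of them, down to -0.82 for ATP7A and -1.25 for ERCC1. Medians were -0.04 for platinum uptake, copper transport and organic cation carriers, where the copper chaperone COX17 was 2.03-fold higher from a parental signal of 77.4, close to the floor. They were 0.19 for metallothioneins, of which MT1H was 2.07-fold higher, and 0.13 for glutathione synthesis and transferases, of which the peroxidase GPX3 was 3.12-fold and GSTA4 2.19-fold higher. Metallothionein sequences are close to each other, and their probe sets can share signal. Nucleotide excision repair, homologous recombination and Fanconi anaemia, mismatch repair and translesion synthesis lists had medians of 0.14, 0.00, 0.27 and 0.06, with none of their 22, 22, 5 and 8 members past 2-fold. The NRF2 target list had a median of -0.05, with HMOX1 its only 1 of 21 members past 2-fold.

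ABCB1, the multidrug efflux pump P-glycoprotein, had a signal of 1801 against 897 in the parental array, 2.01-fold higher by its brighter probe set and 1.02-fold by the other, and it lay under 2-fold in several of the alternative settings, such as the median over its probe sets. ABCC1, ABCC2 and ABCG2 had log2 differences of -0.26, -0.22 and 0.46, ABCA3 was 2.13-fold higher, and the list median was 0.24. Topoisomerases had a median of -0.04, with TOP2A at 0.16 and TOP2B at 0.06, and anthracycline carbonyl reduction genes one of 0.04.

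Individual members of other lists differed from parental in the cisplatin-resistant array while the list medians stayed inside the central 95% of random lists. The vitamin D catabolic enzyme CYP24A1 was 6.58-fold and CYP2B6 5.83-fold lower in the drug metabolism list, which had a median of 0.16. SULT1A1 was 2.55-fold higher there, with probe sets of both signs. Vimentin (VIM) was 2.76-fold higher and lies in a higher stretch of chromosome 10, SPARC was at least 2.24-fold and TGFBI 2.38-fold lower, and the mesenchymal median was -0.05. The epithelial median was 0.18, with E-cadherin (CDH1) 2.14-fold higher and KRT7 3.22-fold and CLDN1 2.45-fold lower. The death receptor FAS was 3.18-fold higher (1.27-fold by its weakest probe set) and PMAIP1, a pro-apoptotic BH3-only protein on chromosome 18, was 2.77-fold lower, with medians of 0.09 for pro-apoptotic and -0.05 for anti-apoptotic genes. Among liver cancer stem cell markers, with a median of 0.07, the aldehyde dehydrogenase ALDH3A1 was 3.08-fold higher and CD24 was 2.71-fold lower. The cytokines CSF1 and CCL20 were 4.09-fold and 3.33-fold lower in the inflammatory list, which had a median of -0.01. MMP1 and its inhibitor TIMP1 were 3.20-fold and 2.66-fold lower, and TIMP1 and the sterol isomerase EBP, 2.22-fold lower, lie in a lower stretch of chromosome X. With the median of neighbouring genes subtracted, a setting added after the data were seen, TIMP1, EBP, VIM and PMAIP1 lay under 2-fold, at -0.46, -0.04, 0.83 and -0.62. So did MAGEC1, S100A3, DDX60, MT1H and ABCB1 in this array, at -0.84, -0.98, 0.93, 0.87 and 0.94. The protease list had a median of -0.14 and cholesterol synthesis 0.13. Cancer-testis antigens went both ways, with MAGEC2 6.06-fold and MAGEC1 2.43-fold lower, MAGEB2 3.25-fold and MAGEA1 2.73-fold higher, and a median of -0.28.

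Further lists had medians near 0 in the cisplatin-resistant array. These were p53 targets at -0.03, cell cycle and proliferation at -0.07, growth factor receptors and ligands at -0.06, heat shock proteins at -0.07 with CRYAB 3.01-fold lower, hypoxia and glycolysis at 0.02, autophagy and lysosome at -0.10, integrins and matrix at -0.13, and ribosomal proteins at -0.03. Annexins and S100 proteins had a median of 0.02, with ANXA6 2.58-fold higher, ANXA3 2.39-fold lower and S100A3 2.13-fold lower. Markers of other cell types had medians of 0.13 for fibroblasts, 0.02 for leukocytes and 0.37 for endothelium. The fibroblast markers went both ways, with lumican (LUM) 10.2-fold higher by 1 probe set and COL6A3 2.51-fold lower. The other LUM probe set was limited by the floor, at least 1.05-fold higher. Simulated arrays for this comparison put 1.70% of unchanged genes past 2-fold. Their normal noise was scaled to the median absolute deviation of the difference between the sublines. Part of the 688 calls would be reached by noise of that size, and noise with the wider tails of that difference could reach more. Another measured probe set lay under 2-fold for GPX3, GSTA4, KRT7, OASL and CD36, while that of TMEM47 gave only a bound under 2-fold. The calls of ETV1, HMGN5, COX17, KRT7, CLDN1, SPARC and OASL lay under 2-fold in several alternative settings. The counts depended on the floor, with 1016 higher and 1022 lower genes at a floor set at the 25th percentile of all values, and 105 and 124 at the 75th.

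The second comparison asked which genes differ between the parental line and its doxorubicin-resistant subline. ABCB1 had the highest fold of the higher genes measured on both arrays by several probe sets of 1 direction, with a signal of 9499 in the doxorubicin-resistant and 897 in the parental array, 10.6-fold higher (5.34 to 10.6-fold over its probe sets). The tight-junction claudins CLDN1 and CLDN4 were 5.50-fold and 3.61-fold higher and the adhesion protein CDH1 3.84-fold higher. The stress-induced transcription factors ATF3 and DDIT3 were 2.91-fold and 2.75-fold higher, ATF3 by 1.38-fold in its weakest probe set. The fibrinogen chains FGB and FGG were at least 25.7-fold and at least 13.1-fold lower, and TF was 12.2-fold lower. A group of neighbouring genes on chromosome X was at or under the floor in this array alone, with SRPX at least 65.2-fold and DYNLT3 at least 37.7-fold lower.

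Of 12605 genes compared, 376 were at least 2-fold higher and 345 at least 2-fold lower in the doxorubicin-resistant array, together 5.72%. Both values were above the floor for 315 higher and 238 lower genes, and 45 higher and 51 lower genes reached 4-fold. The median of a gene's other measured probe sets pointed the same way for 160 of 171 higher and 113 of 124 lower genes, against 69.0% of all genes. It reached 2-fold itself for 67 and 47. After ABCB1, the higher genes were TNFRSF11B at 7.10-fold, the cadherin CDH6 at 5.01-fold, ELAPOR2 at 4.92-fold, the proteoglycan versican (VCAN) at 4.66-fold, the microvillar protein villin (VIL1) at 4.47-fold, TRIM15 at 4.34-fold and MACROD1 at 4.31-fold. The lower genes after TF included SPIRE1 at 5.98-fold, the protein kinase A inhibitor PKIB at 4.92-fold, the methyltransferase BHMT2 at 4.48-fold, the potassium channel subunits KCNE3 and KCNMB4 at 4.20-fold and 3.91-fold, and the protocadherin PCDH7 at 4.09-fold. For MACROD1, KCNE3, PCDH7 and KCNMB4 the probe set with the smallest difference showed only 1.08-fold, 1.02-fold, 1.12-fold and 1.12-fold. For CDH6 and VIL1 it showed 1.47-fold and 1.51-fold, and for VCAN and SPIRE1 at least 1.58-fold and at least 1.61-fold. From under the floor in the parental array, TMEM98 was at least 19.2-fold, APOB at least 10.6-fold, TMEM132D-AS1 at least 10.3-fold and GIPC2 at least 8.41-fold higher. TSPAN7 and MID1IP1, neighbours of SRPX on chromosome X, were at least 29.1-fold and at least 27.9-fold lower.

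ABCB1 was followed in the ABC efflux list by its paralog ABCB4 at 2.76-fold and ABCA3 at 2.05-fold, while ABCC1, ABCC2 and ABCG2 had log2 differences of -0.29, -0.00 and 0.13. The list median was 0.10 over 11 genes, inside the central 95% of random lists. ABCB1, ABCB4, ELAPOR2, CLDN4 and POR, the cytochrome P450 reductase at 2.19-fold, lie in a stretch of chromosome 7 whose 122 compared genes had a median log2 difference of 0.86. When the median of the neighbouring genes was subtracted, a setting added after the data were seen, the log2 difference of ABCB1 went from 3.40 to 1.79, and ELAPOR2, CLDN4, POR and ABCB4 lay under 2-fold at 0.89, 0.78, 0.44 and -0.22. The drug targets TOP2A and TOP2B had log2 differences of -0.44 and -0.20, and topoisomerases a median of -0.09. Anthracycline carbonyl reduction genes had a median of 0.02 and NRF2 targets -0.01, with none of the 21 NRF2 targets past 2-fold. The transporters SLC31A1, ATP7A and ATP7B differed by 0.38, -0.16 (-1.07 by its other probe set) and -0.25, GSTP1 by 0.07 and ERCC1 by -0.17.

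**Figure D2:**
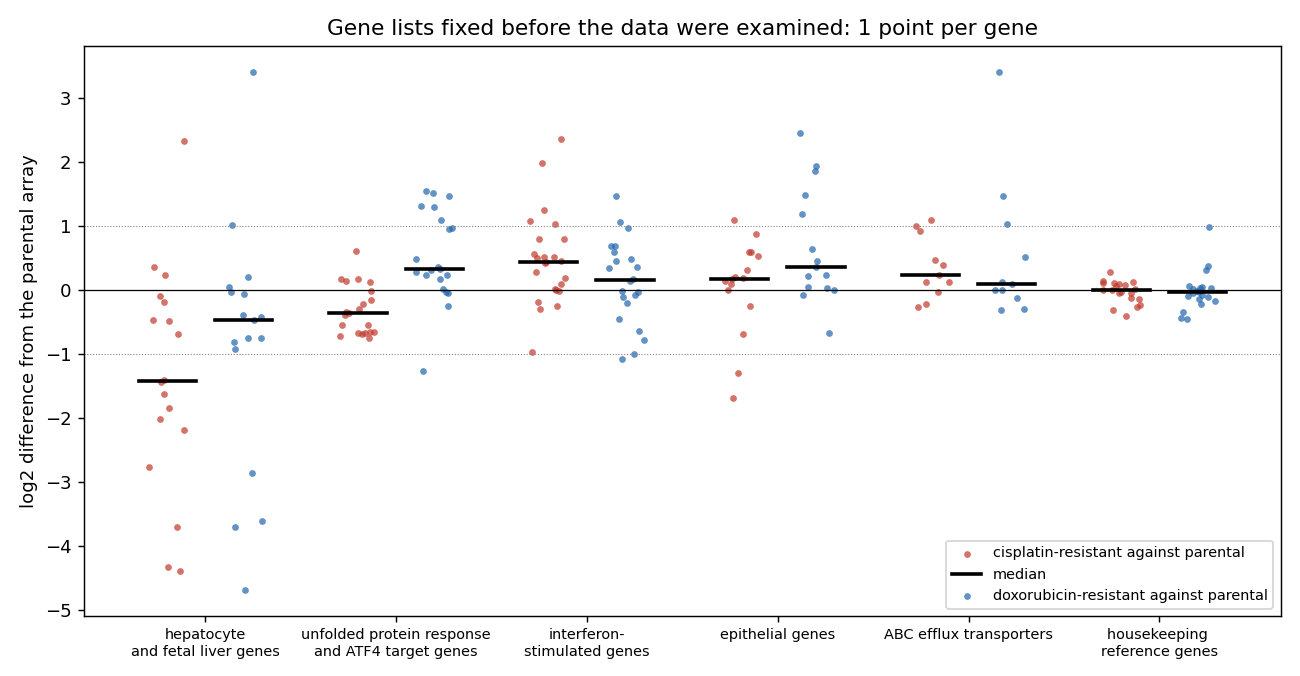
Log2 difference from the parental array (y axis) of each compared member of 6 gene lists (x axis), in red for the cisplatin-resistant and in blue for the doxorubicin-resistant array; 1 point is a gene, black bars are list medians and dotted lines mark 2-fold. The hepatocyte medians are -1.42 and -0.48, and the unfolded protein response and ATF4 medians lie on opposite sides of 0, at -0.36 and 0.33.

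The unfolded protein response and ATF4 target list had a median log2 difference of 0.33 in the doxorubicin-resistant array, which 99.99% of random lists lay below. Of its 21 genes, 6 were higher, 1 lower and 14 within 2-fold; the higher ones included the mTOR inhibitor DDIT4 at 2.87-fold and the asparagine synthetase ASNS at 2.49-fold. The poly-A spikes were lower in this array, as given above. The epithelial list had a median of 0.36 over 15 genes, which 99.9% of random lists lay below, with 5 higher, including CLDN7 at 2.79-fold, and none lower. The mesenchymal list had a median of -0.34, with 12 of its 13 genes below the parental value and SPARC at least 2.24-fold lower. The hepatocyte list had a median of -0.48 over 17 genes, below all random lists, with 4 lower, 2 higher and 11 within 2-fold.

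Cancer-testis antigens had a median of -0.61 over 9 genes in the doxorubicin-resistant array, and 3 were lower, MAGEA12 at 7.28-fold, MAGEC1 at least 3.11-fold and MAGEA6 at 2.33-fold. The MAGEA genes are near-identical copies whose probe sets can share signal, and these genes lie in a lower stretch of chromosome X. With the neighbouring genes subtracted, MAGEA6 lay under 2-fold at -0.66, and MAGEA12 and MAGEC1 at -2.19 and -1.10. The Wnt list had a median of -0.31 over 12 genes, with glutamine synthetase (GLUL) 2.61-fold and the feedback inhibitor AXIN2 2.22-fold lower. Integrins and matrix genes had a median of -0.19, although CCN2, a secreted matricellular protein, had a log2 difference of 1.32, ITGB4 and LAMB1 were 2.21-fold and 2.10-fold higher and COL4A5 was at least 2.32-fold lower. With the neighbouring genes subtracted, ITGB4 and LAMB1 lay under 2-fold at 0.89 and 0.70, and COL4A5, limited by the floor, at -0.92. Hypoxia and glycolysis genes had a median of 0.13, which turned to -0.15 when probe sets marked as shared or cross-hybridising were left out. These were the 8 of 42 lists outside the central 95%, where 2.1 would lie if list members varied independently.

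Growth factor genes went both ways in the doxorubicin-resistant array, with a median of -0.00. The EGF receptor ligands EREG and TGFA were 3.38-fold and 2.92-fold higher, and the platelet-derived growth factor PDGFC was 7.03-fold lower. Among p53 targets, with a median of 0.05, the stress cytokine GDF15 was 3.28-fold higher (1.26-fold by its other measured probe set), and PLK2 and PHLDA3 were 3.28-fold and at least 3.27-fold lower, the latter 1.19-fold by its other measured probe set. The repair genes XPC and RAD18 were 2.12-fold and 2.21-fold lower and, with the autophagy enzyme ATG7 at 2.47-fold, lie in a stretch of chromosome 3 where 67 compared genes had a median of -0.85. With the neighbouring genes subtracted they lay at -0.79, -0.19 and -0.46. Their lists had medians of 0.02 for nucleotide excision repair, -0.12 for translesion synthesis and -0.05 for autophagy and lysosome. The matrix proteases MMP2 and MMP7 were at least 8.41-fold and 2.30-fold lower, with a list median of -0.18. CSF1 was 3.85-fold and the chemokine CXCL5 2.76-fold lower, the aminopeptidase ANPEP was 4.28-fold higher, FAS was 2.43-fold higher and BMF 2.16-fold lower, and UGT1A6 was 2.18-fold higher. Their lists had medians of 0.05 for inflammatory genes, 0.02 for stem cell markers, 0.02 for pro-apoptotic genes and -0.06 for drug metabolism.

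**Figure D3:**
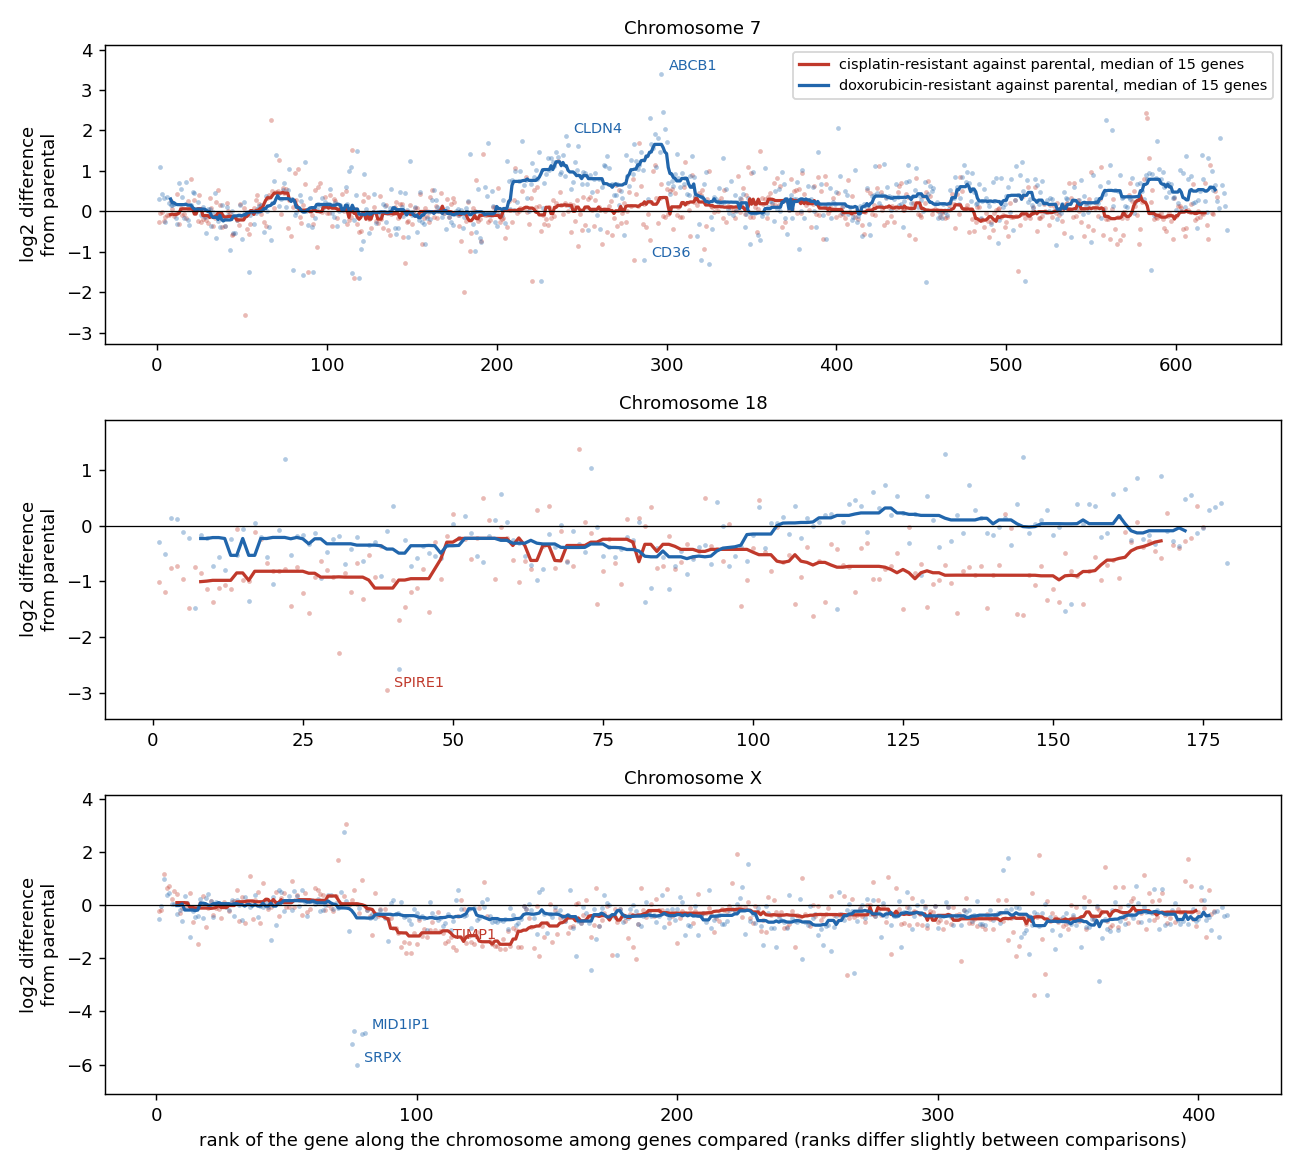
Log2 difference from the parental array (y axis) of compared genes in their order along chromosomes 7, 18 and X (x axis, rank among compared genes), in red for the cisplatin-resistant and in blue for the doxorubicin-resistant array; points are genes and lines are medians of 15 neighbouring genes. The blue line lies above 0 around ABCB1 and the red line lies below 0 along chromosome 18, where the median over genes is -0.72.

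Interferon-stimulated genes had a median of 0.15 in the doxorubicin-resistant array, inside the central 95%, with ISG20 and OASL 2.76-fold and 2.08-fold higher and IFI6 and USP18 2.12-fold and 2.00-fold lower. Antigen presentation genes had a median of 0.11 and fatty acid genes 0.06, with CD36 at least 2.31-fold lower. Heat shock proteins had a median of -0.15, with the small heat shock protein CRYAB 4.62-fold and HSPA6 at least 2.30-fold lower. Medians were 0.18 for metallothioneins, 0.11 for glutathione genes, -0.00 for platinum carriers, 0.09 for homologous recombination, 0.15 for mismatch repair, -0.06 for anti-apoptotic genes, -0.03 for cell cycle genes and 0.10 for Notch genes. They were -0.05 for cholesterol synthesis, -0.05 for annexins and S100 proteins (ANXA6 at least 2.15-fold lower, ANXA13 at least 2.02-fold higher), 0.03 for ribosomal proteins and 0.08 for the respiratory chain. Fibroblast, leukocyte and endothelial markers had medians of -0.31, -0.05 and -0.16, with COL6A3 10.2-fold lower and LUM 4.53-fold higher. Another measured probe set lay under 2-fold for RAD18, ATG7, FAS, EREG, TGFA, HSPA6, OASL and CD36, and the calls of RAD18, FAS, TGFA, ATF3, HSPA6, OASL, USP18, CD36, MMP2, ANXA6 and KCNMB4 lay under 2-fold in several alternative settings. With the neighbouring genes subtracted, UGT1A6 lay under 2-fold at 0.92, as did HSPA6 and ANXA13, both limited by the floor, at -0.82 and 0.79. The counts depended on the floor here too, with 912 higher and 1180 lower genes at the 25th percentile and 160 and 99 at the 75th.

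Both resistant sublines were next compared for shared differences from the parental line. TNFRSF11B, LRATD2, TMEM47, TMEM98, APOB and LUM were higher in both and TF, FGB, FGG, FGF13, NRIP1 and ABTB3 lower in both. The transmembrane protein TMEM98 was at least 5.44-fold higher in the cisplatin-resistant and at least 19.2-fold higher in the doxorubicin-resistant array, and TMEM47 at least 8.35-fold and at least 6.64-fold. LRATD2 was 4.45-fold and 4.24-fold higher. Another probe set of TMEM47, also limited by the floor, showed at least 1.83-fold in the cisplatin-resistant and at least 1.19-fold in the doxorubicin-resistant array. The smallest difference over the probe sets of LRATD2 was 1.35-fold and 1.18-fold. ABTB3 was 7.97-fold and 6.66-fold lower, and NRIP1 at least 10.2-fold lower in each.

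Of 12339 genes compared in both, 105 were at least 2-fold higher and 104 at least 2-fold lower in both sublines, whereas 9 were higher with cisplatin and lower with doxorubicin resistance and 7 the reverse. Independent lists of these sizes would share 9.52 higher and 9.17 lower genes. The comparisons share the parental array, however, and 200 simulations of unchanged arrays gave means of 18.8 higher and 38.0 lower shared genes with normal noise, and 104 and 173 with noise resampled from the difference between the sublines. The observed covariance of the log2 differences was 0.117, against 0.0843 and 0.162 in these simulations, so it lay 0.0325 above the former and differed by -0.0449 from the latter. The resampled noise includes any real differences between the sublines, so its 104, 173 and 0.162 are not values of array noise alone. The single parental array could not be split, so no shared effect of resistance can be separated from it.

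The last comparison set the doxorubicin-resistant directly against the cisplatin-resistant subline, without the parental array. ABCB1 was 5.27-fold higher in the doxorubicin-resistant array by its brighter probe set and 5.21-fold by the other, and its log2 difference of 2.40 became 1.05 with the neighbouring genes subtracted. ALB was at least 40.5-fold higher there (a log2 difference of at least 1.58 by its weakest measured probe set), CLDN1 13.4-fold higher, and the acute-phase protein ORM1 at least 11.8-fold higher. In the other direction, PDGFC was 11.5-fold (at least 1.62-fold by its other probe set) and NNMT 10.8-fold lower in the doxorubicin-resistant array. DYNLT3 and SRPX were at least 55.2-fold and at least 52.4-fold lower. The ATF4 pathway genes CHAC1, DDIT3 and SESN2 were 3.93-fold, 3.38-fold and 3.24-fold higher.

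Of 12604 genes compared between the sublines, 385 were at least 2-fold higher and 416 at least 2-fold lower in the doxorubicin-resistant array, together 6.36%. The median of a gene's other measured probe sets pointed the same way for 172 of 179 and 163 of 175 of them, against 69.3% of all genes. It reached 2-fold itself for 68 and 52. VCAN was 7.73-fold, the transcription factor ONECUT2, on chromosome 18, 6.74-fold, CROT, a neighbour of ABCB1 on chromosome 7, 5.72-fold, and EREG 5.64-fold higher. BHMT2, KCNMB4, the sialyltransferase ST8SIA4 and SULT1A1 were 7.13-fold, 4.81-fold, 4.06-fold and 3.98-fold lower. The probe set with the smallest difference showed 1.06-fold for CROT, 1.04-fold for KCNMB4, 1.19-fold for SULT1A1 and 1.65-fold for FGB. For VCAN and LUM it was limited by the floor, at least 1.58-fold and at least 1.05-fold. The unfolded protein response and ATF4 list had a median of 0.71, above all random lists, with 9 higher, 1 lower and 11 within 2-fold. The hepatocyte list had a median of 0.65, also above all random lists, with 6 higher and 2 lower of 16, although FGB was at least 3.79-fold lower. Epithelial genes had a median of 0.21 and Notch genes 0.33. Fatty acid genes had a median of -0.40, cancer-testis antigens -0.86 and fibroblast markers -0.62, and these 7 of 42 lists lay outside the central 95%.

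The other 35 lists had medians from -0.42 to 0.13. Interferon-stimulated genes were among them, with a median of -0.12, and IFI27 was 7.98-fold and DDX60 2.44-fold lower in the doxorubicin-resistant array. CYP2B6 was 9.44-fold and CYP24A1 4.15-fold higher, HMOX1 3.57-fold higher, GDF15 5.83-fold higher (1.39-fold by its other measured probe set) and the chemokine CCL20 5.49-fold higher. VIM was 3.18-fold lower, and COL6A3 and LUM were 4.05-fold and 2.26-fold lower. TOP2A and TOP2B had log2 differences of -0.60 and -0.26, SLC31A1 of 0.50 and ERCC1 of 0.14.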

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

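These results were picked out because the sublines differed from the parental array in opposite directions, each by at least 2-fold; no test of an explanation was run for them, either before or after the results were seen. The difference between the sublines was not tested, since each was measured on 1 array. Of the 12339 genes compared in both, 16 met the rule, 9 with cisplatin resistance higher and 7 with doxorubicin resistance higher. In 200 simulations of unchanged arrays, normal noise gave means of 0.02 and 0.035 such genes, at most 1 each, and noise resampled from the subline difference, which these genes themselves widen, gave 3.5 and 3.28, at most 10 and 8.

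Genes higher in the doxorubicin-resistant and lower in the cisplatin-resistant array were led by ALB, the main plasma protein made by hepatocytes, with a log2 difference between the sublines of at least 5.34 (doxorubicin-resistant minus cisplatin-resistant). Most of it lay in the cisplatin-resistant array, where ALB differed from parental by at most -4.33. In the doxorubicin-resistant array ALB differed from parental by 1.01, close to the threshold. The tight-junction gene CLDN1 differed by 3.75, the prostacyclin synthase PTGIS by 3.66, the acute-phase gene ORM1 by at least 3.56 and the insulin-like growth factor binding protein IGFBP1 by 3.42. The transcription factor ONECUT2, on chromosome 18, differed by 2.75 and the engulfment adaptor ELMO1 by 2.50.

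Genes lower in the doxorubicin-resistant and higher in the cisplatin-resistant array were led by the secreted epithelial protein BPIFB1, with a log2 difference of -4.47, and LINC00326, with -3.97. The neuropeptide NMU differed by -3.05, the ribonuclease RNASE1 by -2.70, CDCA7L by at most -2.62 and ANXA6 by at most -2.47, as both were under the floor in the doxorubicin-resistant array. The phospholipase PLA2G4A, in a lower stretch of chromosome 1, differed by -2.28, SYNGR1 by -2.18 and RGCC by -2.17.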

How the results depend on the processing

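All settings here were chosen in advance, except the subtraction of neighbouring genes, the removal of shifted segments and the use of the settings on chromosome medians, which were chosen after seeing the data. No paired analysis was possible because each group had 1 array. Of 131 counts under the alternatives, 79 stayed within 1.5 times the reported count and 52 moved, as follows, with higher before lower genes and in the order cisplatin-resistant against parental, doxorubicin-resistant against parental, doxorubicin-resistant against cisplatin-resistant, and both sublines against parental. A 1.5-fold threshold gave 1180 and 1048, 1145 and 1083, 1149 and 1247, and 391 and 397 genes, and a 4-fold threshold 27 and 27, 45 and 51, 39 and 52, and 7 and 12. A floor at the 25th percentile gave 1016 and 1022, 912 and 1180, 941 and 1248, and 330 and 410, a floor at the 75th percentile 105 and 124, 160 and 99, 183 and 138, and 25 and 26, and no floor 2001 and 1951, 1796 and 2282, 1789 and 2366, and 943 and 826. These follow from how the settings are made, as thresholds and floors admit or remove small and low differences. The floor as a pseudocount gave 224 and 217 genes in the cisplatin-resistant array and 57 and 61 in both sublines. The median over probe sets gave 209 higher genes in the cisplatin-resistant, 242 higher and 206 lower in the doxorubicin-resistant array, 238 and 248 between the sublines, and 60 and 67 in both sublines. Keeping only genes above the floor on all arrays left 56 of the 104 genes lower in both sublines, since it removes those at or under the floor in a subline. Quantile normalization, median alignment, leaving out probe sets with the suffixes _x_at and _s_at, subtracting the neighbouring genes and leaving out shifted segments moved no count past 1.5 times. Lists outside the central 95% numbered 7 to 10 and 7 to 10 against parental and 5 to 8 between the sublines. Of 1120 list medians under the alternatives, 978 stayed the same within the spread of random lists, 141 moved and 1 reversed, the hypoxia and glycolysis list in the doxorubicin-resistant array, at -0.15 without _x_at and _s_at probe sets. Of 2293 values of named genes, 1888 stayed the same, 402 moved and 3 reversed: SULT1A1 in the cisplatin-resistant array, at -0.40 without those probe sets, and ABCB4, at -0.22 against parental and -0.31 between the sublines after its neighbours were subtracted, which removes the shift of the surrounding stretch. The cause was not tested for the list and SULT1A1. Of 216 named values past 2-fold, 61 stayed past it in every setting chosen in advance, 46 in every setting that could compare them, and 109 did not in at least 1; a gene at the floor on both arrays was not compared, as ALB without _s_at probe sets. Values near background were noisier, as the spread over genes was 0.465 among the dimmest and 0.272 among the brightest of 3 equal groups of genes in the cisplatin-resistant array against parental.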

Other observations

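The windows of neighbouring genes were planned; the use of other scalings on chromosome medians, the subtraction of neighbouring genes and the tests of ABCB1 and ABCB4 alone, of the genes flanking the chromosome X run and of DNA gain or loss were chosen only after the result was seen. Differences from the parental line clustered along chromosomes. In the cisplatin-resistant array 6 higher and 8 lower stretches held 498 genes, 3.93% of the genes placed, and 131 of the 688 genes past 2-fold. They included a lower stretch of chromosome X of 89 genes from ATP6AP2 to ZXDB, with a median log2 difference of -0.94 and 40 genes past 2-fold, among them the histone demethylase KDM6A at -1.57 and the methyltransferase SUV39H1 at -1.55. A higher stretch of chromosome 10 from GDI2 to MSRB2 had a median of 0.60 over 54 genes, with VIM at 1.47 and GATA3, a transcription factor, at 1.63. Chromosome 21 had a median of 0.41 over 138 genes.

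In the doxorubicin-resistant array 4 higher and 7 lower stretches held 428 genes, 3.40% of the genes placed, and 108 of the 720 genes past 2-fold. The lower stretch of chromosome 3 from LOC105379426 to FGD5-AS1 had a median of -0.85, and 62 of its 67 genes were below the parental value. The same genes had a median of -0.00 in the cisplatin-resistant array. Chromosome X as a whole had medians of -0.37 in the doxorubicin-resistant and -0.36 in the cisplatin-resistant array. Between the sublines its median was -0.00. Both values against parental use the single parental array, so a shift of that array alone cannot be told apart from a shift in both sublines. In the direct difference between the sublines, 9 higher and 10 lower stretches held 664 genes. They included chromosome 7 from NIPSNAP2 to RBM48 with a median of 0.82, chromosome 18 from MIR924HG to TXNL4A with 0.76 and chromosome 3 from LOC105379426 to CAPN7 with -0.80.

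The genes around ABCB1 on chromosome 7 were higher together in the doxorubicin-resistant array. The stretch from PSPH to SGCE held 122 compared genes with a median log2 difference of 0.86, of which 110 were above the parental value, and the same genes had a median of 0.09 in the cisplatin-resistant array. The median was at least 0.85 under both other scalings. These act on all genes of an array, so they could hardly have removed a shift confined to a stretch. Single misreporting probe sets do not account for the shift, as 79 further probe sets of the stretch, not used to find it, had a median of 0.79. The 77 of them from genes other than ABCB1 and ABCB4 had a median of 0.72. Those genes alone could not have set the median of 122 genes, so this value decides nothing further. ABCB1 stood 2.54 above the median of the stretch, but 1.79 above its nearest genes, and 1.05 above them between the sublines. A gain of DNA that carries ABCB1 is a candidate explanation, but DNA was not measured, and a gain cannot be told apart from shared chromatin control by the 0.86 median.

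On chromosome X, 7 consecutive genes that were above the floor in the parental array (XK, DYNLT3, SYTL5, SRPX, RPGR, TSPAN7 and MID1IP1) were all at or under it in the doxorubicin-resistant array, with a median log2 difference of at most -4.80, and all were above it in the cisplatin-resistant array. The longest such run in 1000 shuffles of gene order was 6, so a chance run is argued against, although XK and RPGR were close to the floor in the parental array, with signals of 151 and 83.2. The 10 flanking genes had a median of -0.17, which argues against lower signal of the whole region. Those beyond MID1IP1 lay at -0.20 to -0.50 and those before XK at -0.13 to 0.50. Of them, LOC105373150 and MED14OS were under the floor in the doxorubicin-resistant array, so their -0.13 and -0.35 are bounds. BCOR and PRRG1, the nearest flanking genes, had signals of 758 and 517 against 871 and 462 in the parental array. A deletion present in nearly all cells may underlie the run, but a deletion and silencing cannot be told apart by the median of -4.80, since no DNA was measured.

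Genes on chromosome 18 were lower in the cisplatin-resistant array, with a median log2 difference of -0.72 over 175 genes, of which 90.3% were below the parental value; in the doxorubicin-resistant array the median was -0.18. The shift was uneven, at -0.92 from USP14 to GATA6-AS1, -0.35 from GATA6 to RMP24, where the doxorubicin-resistant array had -0.43, and -0.74 from PIK3C3 to SLC66A2. The median was at most -0.73 under both other scalings. These act on all genes of an array, so they could hardly have removed a shift of a single chromosome. Noise of dim probe sets does not account for the shift, as the brightest 59 genes had a median of -0.73. The chromosome carries the SMAD inhibitor SMAD7 at -1.62 as well as SPIRE1 at -2.96 and PMAIP1 at -1.47. With the neighbouring genes subtracted, SPIRE1 stayed at -1.91 and PMAIP1 lay at -0.62. SPIRE1 was also at -2.58 in the doxorubicin-resistant array. Loss of DNA from all or parts of the chromosome may underlie the shift, but such a loss and shared regulation cannot be told apart by the -0.72 median without a DNA measurement.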
